A study of Danio rerio with 10 samples.

How the data were processed

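RNA of single cells from the trunk of zebrafish larvae was measured by 10x Genomics 3' sequencing, in 10 libraries of 5 groups. Per the labels' protocols, a piece of trunk was digested with trypsin and live cells were sorted by a viability dye, so shares of cells follow digestion and sorting. The authors deposited raw UMI counts per gene and barcode as filtered matrices. Reads were counted with Cell Ranger 7.1 on GRCz11, per the submitters' processing notes, while the file headers name cellranger 6.0.1. The annotation release, the cell-calling settings and whether introns were counted are not given in the sources used here. The files hold 30423 features with symbols, and UMIs of near-identical paralogs such as globin genes may be split between copies by the authors' counting.

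Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept. Scrublet's score was computed with numpy 2.4.6 and scipy 1.17.1 for barcodes with at least 500 genes, from 2 simulated doublets per barcode and an expected rate of 8%. Scores above 0.2 (0.816% to 1.93% of scored barcodes per library) were called doublets and left out. Counts scaled to 10000 per barcode and log-transformed gave 30 components of 2000 variable genes, and a graph of 20 neighbours was split by leidenalg 0.10.2 at resolution 2 into 70 clusters. A cluster was named from fixed markers where at least 3 of them, and 50% of the list, had a log2 fold above 1 over other cells and were detected in 10% of its cells, and where its 10 leading genes held more of its own markers than of another class. These thresholds were set after the data were seen.

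Counts were summed per library and class, for libraries with at least 20 cells of it. All groups were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr and the quasi-likelihood test, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. Shares were tested by the same test on cell counts with the cells of the library as offset, over 18 classes. Camera in limma 3.58.1 compared each of 35 lists with the other genes of the class, adjusted over lists and the 4 contrasts against unlesioned larvae. Symbols matched as written for 1030 of 1102 list and marker entries, and by synonym for 52. The labels do not say that libraries came from separate clutches, so p-values measure only the spread between these libraries, which may be technical. Free RNA in droplets adds UMIs of abundant genes to cells that do not express them.

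Groups, tests of the comparisons, markers, lists, the rule for named genes and the first alternatives below were chosen before the data were examined. The rule takes, among called genes with both libraries beyond both unlesioned libraries and a mean of at least 30 CPM in one group, the 4 largest rises and 3 largest falls by fitted log2 change, leaving out symbols with a colon or starting with LOC or ENSDARG. Fitted changes of genes with at most 3 UMIs in a group are no bounds, so no order of size is given. It adds 2 members with the smallest p of each described list, and 8 fixed genes in fibroblast-like cells. A gene that the rule takes is not reported here. Which lists are described was chosen after their values were seen. These alternatives were RLE factors, DESeq2 1.42.0, no gene filter, a replicate block, the 2 compared groups alone, a cell filter of 500 genes and 10% mitochondrial UMIs, doublets kept, resolution 1, shares with TMM factors or without the largest class, fry, an estimated correlation, and each library left out. Added after the data were seen were fits without the cluster that rose most or the 24hpl libraries, and cells of named classes as the total.

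The tests were tested on simulated data. For fibroblast-like cells at 6hpl, over 12188 genes, edgeR recovered 7% of genes changed 2-fold and 57% of those changed 4-fold, and 3.52% of calls were false. For shares at 24hpl, 70% of classes changed 8-fold were called. A planted list was called in 3 of 3 runs at 12hpl, as were 4 of 405 other tests. Camera's preset correlation was not tested.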

Results

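The series measured the RNA of single cells from the trunk of zebrafish larvae after transection of the spinal cord, after which larvae recover swimming. The larvae carried a transgene that drives EGFP from pdgfrb regulatory sequence, pdgfrb being a receptor of fibroblasts and mural cells. There were 5 groups of 2 libraries each: unlesioned larvae, and larvae at 6, 12, 24 and 48 hours after the lesion, written 6hpl, 12hpl, 24hpl and 48hpl. All larvae were 4 days old except those at 48hpl, which were 5 days old, so that age and time cannot be separated there. The total count per library ranged from 46990931 UMIs (24hpl 2, replicate 2 of that group) to 100852747 UMIs (48hpl 2).

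Of 116435 barcodes, 108628 were kept as cells, and 50917 of these fell in 19 classes, each called X-like from its markers. Cells of unnamed clusters made up 48.3% ± 3.3 of the unlesioned libraries, 57.7% ± 8.53 at 6hpl, 48.9% ± 8.31 at 12hpl, 45.7% ± 6.58 at 24hpl and 58.9% ± 4.69 at 48hpl (SD, n = 2). Some unnamed clusters were mostly of 1 library of a group: cluster 3 was 28.9% of unlesioned 1 and 0.914% of unlesioned 2, cluster 1 0.0973% and 17.9%, cluster 2 6.33% of 6hpl 1 and 37.7% of 6hpl 2, and cluster 10 16% of 24hpl 1 and 1.81% of 24hpl 2. Cluster 0 was 34.8% and 45.2% of the 48hpl libraries and at most 3.64% elsewhere. Throughout, ± on a share or on CPM (TMM-scaled counts of a class) is the SD over 2 libraries. Values in brackets after a gene are its log2 change ± standard error, with n = 2 libraries per group, and genes written as higher or lower, risen or fallen passed an adjusted p of 0.05. For genes without a UMI in a group the fold is a bound against a floor of 3 UMIs over that group, and for genes with 1 to 3 UMIs it is the ratio with its 95% counting interval. Intervals and floors cover counting error only. Genes are named by the symbols of the files.

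The first question was which cell types changed in abundance after the lesion. Macrophage-like cells, the tissue phagocytes, were 0.059% ± 0.0459 of cells in unlesioned larvae, 0.368% ± 0.0726 at 6hpl, 0.891% ± 0.453 at 12hpl, 2.03% ± 0.172 at 24hpl and 1.02% ± 0.994 at 48hpl. Their share rose at 12hpl (log2 change 3.88 ± 0.95, adjusted p = 0.028), 24hpl (5.07 ± 1.0, adjusted p = 0.0024) and 48hpl (4.07 ± 0.96, adjusted p = 0.021). Neutrophil-like cells, which arrive early at wounds, went from 1.27% ± 0.286 to 6.98% ± 0.341 at 24hpl (log2 change 2.45 ± 0.62, adjusted p = 0.0079). At 24hpl the share fell for erythrocyte-like cells (log2 change -5.39 ± 1.01, adjusted p = 0.0024), from 1.97% ± 1.93 to 0.0462% ± 0.0039, and for neuron-like cells (-4.23 ± 0.95, adjusted p = 0.0048), from 9.95% ± 6.39 to 0.527% ± 0.0993. It also fell for Schwann and satellite glia-like cells (log2 change -3.0 ± 0.77, adjusted p = 0.0079) and lateral line hair cell-like cells (-1.93 ± 0.67, adjusted p = 0.040). Without 1 library the 12hpl call of macrophage-like cells was lost for unlesioned 1, 6hpl 1 or 2, 12hpl 1 (adjusted p = 0.090 to 0.18) and the 48hpl call for unlesioned 1, 6hpl 1 or 2, 48hpl 1 (adjusted p = 0.082 to 0.14). Both calls were also lost at the coarser clustering (log2 change 2.8 and 2.8, adjusted p = 0.090 and 0.091), with the 2 compared groups alone (adjusted p = 0.17 and 0.35) and with the replicate number as a block (adjusted p = 0.055 and 0.0516). At 24hpl calls were lost for neuron-like cells without 24hpl 2 (adjusted p = 0.0507), Schwann and satellite glia-like cells without 24hpl 2 (adjusted p = 0.10), neutrophil-like cells without unlesioned 2, 24hpl 2 (adjusted p = 0.0507 to 0.065) and hair cell-like cells without unlesioned 2, 12hpl 1 or 2, 24hpl 1 or 2 (adjusted p = 0.067 to 0.23), and hair cell-like cells lost theirs under these 3 settings (adjusted p = 0.061 to 0.13) and without the largest class (adjusted p = 0.062). The log2 change of macrophage-like cells was 3.27 without unlesioned 1, 5.01 without unlesioned 2 and 3.24 without 12hpl 1 at 12hpl, 4.46 without unlesioned 1 and 6.2 without unlesioned 2 at 24hpl and 3.46 without unlesioned 1, 5.2 without unlesioned 2, 2.4 without 48hpl 1 and 4.83 without 48hpl 2 at 48hpl. That of erythrocyte-like cells at 24hpl was -3.69 without unlesioned 1 and -6.15 without unlesioned 2, that of neuron-like cells -3.36 without unlesioned 2, and that of Schwann and satellite glia-like cells -4.13 without 24hpl 1 and -2.4 without 24hpl 2.

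Neural progenitor-like cells, the radial glia that line the spinal canal, were 1.84% ± 0.00176 of cells in unlesioned larvae and 0.438% ± 0.0939 at 6hpl (log2 change -2.06 ± 0.61, adjusted p = 0.096), a change that did not pass. Fibroblast-like cells were 4.35% ± 3.83 in unlesioned larvae and 2.45% ± 0.512 at 24hpl, and basal epidermis-like cells 10.4% ± 3.05 and 12.6% ± 0.968. None of the changes of these 2 classes against unlesioned larvae was called by edgeR (adjusted p = 0.45 to 0.88 and 0.21 to 0.91 over the 4 times). At 6hpl edgeR called 0 of 18 classes, with 3 at an unadjusted p under 0.05, and DESeq2 called 2.

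**Figure D1:**
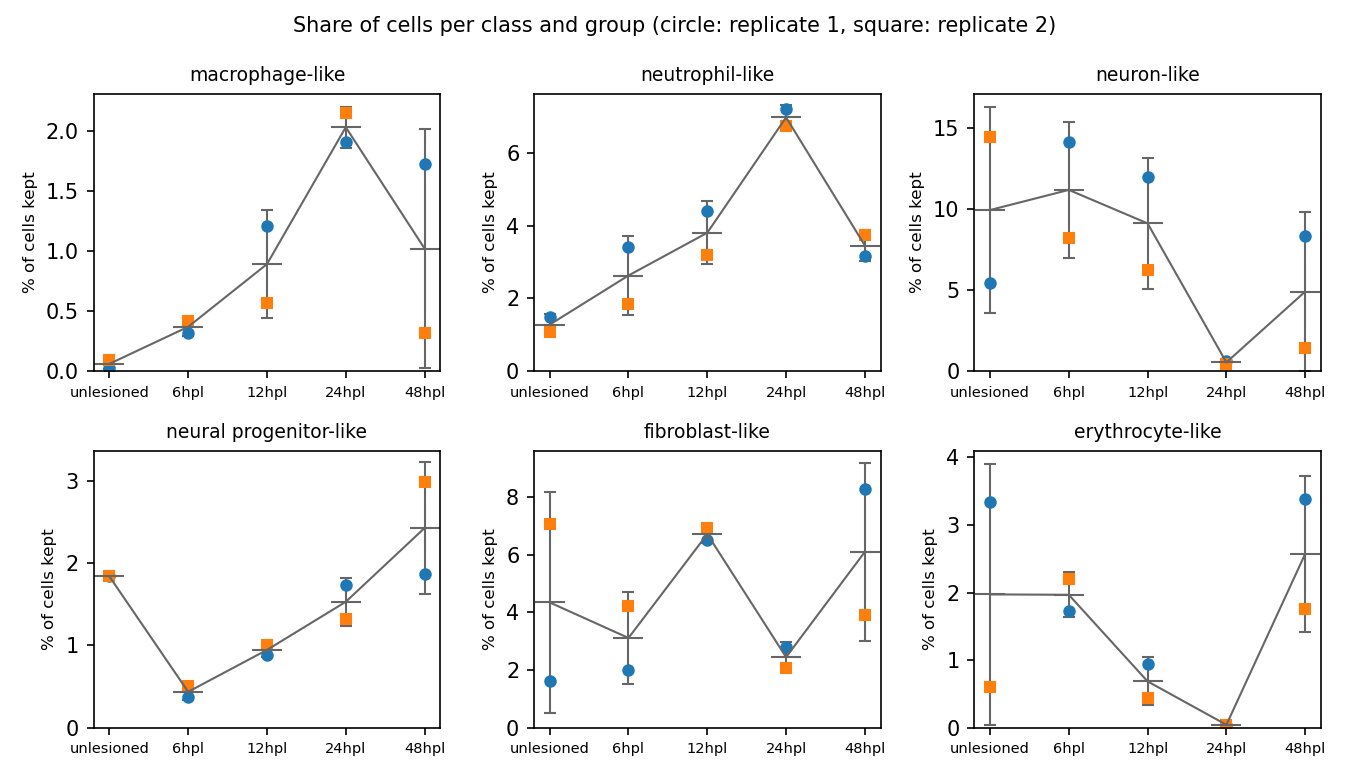
Share of cells (percent of cells kept, vertical axes) in 6 classes against group (horizontal axes). Circles and squares are the 2 libraries, line and bars their mean ± SD. Macrophage-like cells were 2.03% and neuron-like cells 0.527% of cells at 24hpl.

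In fibroblast-like cells at 6hpl, genes that rose included dkk1a (at least 29.5-fold higher, adjusted p = 1.5e-04), an inhibitor of Wnt signalling, the cytokines il11a (at least 25.8-fold higher, adjusted p = 3.4e-04) and il11 (147-fold, interval 26.1 to 5825, adjusted p = 1.5e-04), and the chemokine cxcl19 (215-fold, interval 38.3 to 8505, adjusted p = 1.5e-04). Of the fibroblast genes fixed beforehand, the fibronectin gene fn1b (1.9 ± 0.53, adjusted p = 0.039) rose and the fibrillar collagen gene col1a1a (-1.01 ± 0.29, adjusted p = 0.0481) fell. Also lower were gfap (-4.26 ± 0.96, adjusted p = 0.016), krt91 (-3.61 ± 0.66, adjusted p = 0.0056) and mbpa (-3.36 ± 0.45, adjusted p = 9.1e-04), which are genes of glia, epidermis and myelin. Of genes for inflammatory cytokines and targets of NF-kB, 10 of 19 rose (13 adjusted over the list alone), camera adjusted p = 1.7e-10, adjusted p = 0.11 with an estimated correlation. Among them were cxcl8b.1 (5.94 ± 0.47), a neutrophil attractant, and il11a. Of ribosome biogenesis genes, 21 of 28 rose (26 adjusted over the list alone), camera adjusted p = 1.2e-16, adjusted p = 0.46 with an estimated correlation. Examples were npm1a (1.95 ± 0.33) and fbl (1.62 ± 0.28). Of genes of the unfolded protein response, 9 of 22 rose (14 adjusted over the list alone), camera adjusted p = 3.5e-11, adjusted p = 0.26 with an estimated correlation. Examples were manf (2.52 ± 0.29) and dnajb11 (2.03 ± 0.28). Of cell cycle genes, 8 of 32 fell (14 adjusted over the list alone), camera adjusted p = 1.2e-10, adjusted p = 0.47 with an estimated correlation. Examples were rrm2 (-2.41 ± 0.40) and tyms (-1.93 ± 0.39). Of the collagen genes, 6 of 22 fell (7 adjusted over the list alone), camera adjusted p = 5.6e-04, adjusted p = 0.52 with an estimated correlation. Examples were col8a2 (-3.83 ± 0.75) and col5a3b (-3.94 ± 0.87). Neuron transcripts, which mark another cell type, fell with them: 3 of 11 fell (7 adjusted over the list alone), camera adjusted p = 0.0041, adjusted p = 0.62 with an estimated correlation. Examples were snap25a (-2.14 ± 0.45) and stmn2a (-2.18 ± 0.55). The other fixed genes were not called: pdgfrb (0.57 ± 0.25), pdgfra (0.22 ± 0.29), col12a1a (0.21 ± 0.26), col12a1b (0.25 ± 0.27), fn1a (0.69 ± 0.26) and tnc (-0.67 ± 0.26), at adjusted p = 0.12 to 0.69. 1054 of 12188 genes passed, 701 higher and 353 lower. The count was 296 without unlesioned 1, 278 without unlesioned 2, 225 without 6hpl 1 and 319 without 6hpl 2, and 109 without cluster 44. Cluster 5 was the largest of the class in every group except 24hpl, where cluster 44 was. Calls lost without 1 library (adjusted p) were of fn1b (unlesioned 1 or 2, 6hpl 1 or 2, 0.095 to 0.23), col1a1a (unlesioned 1 or 2, 6hpl 1 or 2, 48hpl 1 or 2, 0.060 to 0.40), gfap (unlesioned 2, 6hpl 1 or 2, 0.067 to 0.21), krt91 (6hpl 2, 0.062), fbl (unlesioned 2, 0.0502), rrm2 (6hpl 2, 0.0549), tyms (unlesioned 1, 6hpl 1 or 2, 0.054 to 0.091), col5a3b (unlesioned 2, 6hpl 2, 0.15 to 0.18), snap25a (unlesioned 2, 6hpl 1 or 2, 0.078 to 0.35) and stmn2a (unlesioned 2, 6hpl 1 or 2, 0.10 to 0.41). The fold moved by over 1.5 times, to the log2 change shown, for gfap (unlesioned 2 at -3.17), cxcl8b.1 (unlesioned 2 at 6.76), rrm2 (unlesioned 1 at -1.75), tyms (unlesioned 1 at -1.31), col5a3b (6hpl 2 at -2.29), snap25a (unlesioned 2 at -1.05) and stmn2a (unlesioned 2 at -1.37). At most 3 UMIs, and no fold, were left for gfap (6hpl 2), mbpa (6hpl 2), col8a2 (6hpl 2), col5a3b (6hpl 1) and stmn2a (6hpl 2).

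Genes that rose in fibroblast-like cells at 12hpl included dkk1a (at least 28.5-fold higher, adjusted p = 1.1e-04), cxcl19 (425-fold, interval 76.2 to 16795, adjusted p = 1.3e-05), the coagulation factor f8 (177-fold, interval 31.7 to 7004, adjusted p = 9.4e-06) and il11 (142-fold, interval 25.4 to 5621, adjusted p = 9.3e-05). Fibronectin genes rose, fn1a (1.68 ± 0.27, adjusted p = 0.0012) from 147 ± 21.1 to 468 ± 112 CPM and fn1b (1.81 ± 0.52, adjusted p = 0.027), while col1a1a (-0.90 ± 0.29, adjusted p = 0.0459) fell. Also lower were pvalb8 (-4.4 ± 0.65, adjusted p = 9.0e-04), hbbe1.2 (-4.15 ± 0.90, adjusted p = 0.0069) and mbpa (-4.07 ± 0.44, adjusted p = 1.4e-04). Of unfolded protein response genes, 14 of 22 rose (15 adjusted over the list alone), camera adjusted p = 3.4e-12, adjusted p = 0.26 with an estimated correlation. Examples were manf (3.29 ± 0.28) and dnajb11 (2.83 ± 0.27). Of nuclear genes of oxidative phosphorylation, 19 of 30 rose (28 adjusted over the list alone), camera adjusted p = 1.5e-11, adjusted p = 0.47 with an estimated correlation. Examples were cycsb (2.35 ± 0.32) and uqcrc1 (1.34 ± 0.25). Of inflammatory genes, 8 of 19 rose (9 adjusted over the list alone), camera adjusted p = 6.4e-05, adjusted p = 0.26 with an estimated correlation. Examples were cxcl8b.1 (5.13 ± 0.46) and the leptin gene lepb (43.3-fold, interval 7.65 to 1720, adjusted p = 9.7e-04). Erythrocyte transcripts fell in the same cells: 9 of 9 fell (9 adjusted over the list alone), camera adjusted p = 6.4e-05, adjusted p = 0.48 with an estimated correlation. Examples were hbbe2 (-3.85 ± 0.78) and hbae1 (-3.82 ± 0.80). Fixed genes without a call were pdgfrb (0.13 ± 0.24), pdgfra (-0.30 ± 0.29), col12a1a (0.40 ± 0.26), col12a1b (0.43 ± 0.27) and tnc (0.046 ± 0.26), at adjusted p = 0.28 to 0.92. 2314 of 12188 genes passed, 1421 higher and 893 lower. Left-out libraries gave 1036 without unlesioned 1, 753 without unlesioned 2 and 623 without 12hpl 1, and 73 genes passed without cluster 44, where fn1a stood at -0.13. Leaving out 1 library ended calls (adjusted p) of fn1b (unlesioned 1 or 2, 12hpl 1 or 2, 0.065 to 0.18), col1a1a (unlesioned 1 or 2, 6hpl 1 or 2, 12hpl 1 or 2, 24hpl 1, 48hpl 1 or 2, 0.059 to 0.32), hbbe1.2 (unlesioned 1, 12hpl 1, 0.11 to 0.23), hbbe2 (unlesioned 1, 12hpl 1, 0.080 to 0.086) and hbae1 (unlesioned 1, 12hpl 1, 0.095 to 0.16). Fold moves over 1.5 times were of hbbe1.2 (unlesioned 2 at -5.05, 12hpl 2 at -4.76, unlesioned 1 at -1.19), cxcl8b.1 (unlesioned 2 at 5.97), hbbe2 (unlesioned 2 at -4.67, 12hpl 2 at -4.7, unlesioned 1 at -1.56, 12hpl 1 at -3.24) and hbae1 (unlesioned 2 at -4.69, unlesioned 1 at -1.16).

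In fibroblast-like cells at 24hpl fn1a (2.59 ± 0.27, adjusted p = 6.3e-05) went from 147 ± 21.1 to 877 ± 19.2 CPM, the tenascin gene tnc (1.28 ± 0.26, adjusted p = 0.0050) from 869 ± 43.8 to 2118 ± 154 CPM, and col12a1a (0.86 ± 0.26, adjusted p = 0.032), col12a1b (0.95 ± 0.27, adjusted p = 0.025) and fn1b (1.87 ± 0.53, adjusted p = 0.024) also rose. Higher too were cxcl19 (300.5-fold, interval 53.4 to 11914, adjusted p = 3.3e-05), f8 (216-fold, interval 38.4 to 8596, adjusted p = 9.7e-06), the versican gene vcana (106-fold, interval 28.9 to 881, adjusted p = 1.1e-05) and the leptin gene lepa (90.5-fold, interval 24.6 to 754, adjusted p = 1.4e-04). Lower were the myelin gene mbpa (at least 45.4-fold lower, adjusted p = 7.9e-05) and of the globin genes hbbe1.2 (435-fold, interval 77.8 to 17229, adjusted p = 0.0017) and hbae1 (-7.37 ± 1.15, adjusted p = 9.3e-04). Of unfolded protein response genes, 14 of 22 rose (14 adjusted over the list alone), camera adjusted p = 9.3e-16, adjusted p = 0.26 with an estimated correlation. Examples were manf (3.67 ± 0.29) and dnajb11 (2.88 ± 0.28). Of oxidative phosphorylation genes, 26 of 30 rose (29 adjusted over the list alone), camera adjusted p = 6.7e-13, adjusted p = 0.47 with an estimated correlation. Examples were cycsb (2.18 ± 0.32) and uqcrc1 (1.74 ± 0.26). Of cell cycle genes, 13 of 32 rose (16 adjusted over the list alone), camera adjusted p = 1.4e-04, adjusted p = 0.62 with an estimated correlation. Examples were the mitotic genes ccnb1 (3.98 ± 0.78) and plk1 (2.26 ± 0.50). Transcripts of other cell types fell beside these groups. For erythrocyte genes, 9 of 9 fell (9 adjusted over the list alone), camera adjusted p = 2.8e-09, adjusted p = 0.46 with an estimated correlation. Examples were hbbe1.1 (-6.46 ± 0.97) and hbbe2 (-7.2 ± 1.09). For neuron genes, 9 of 11 fell (9 adjusted over the list alone), camera adjusted p = 1.0e-06, adjusted p = 0.47 with an estimated correlation. Examples were snap25a (28.5-fold, interval 9.46 to 140.3, adjusted p = 5.7e-04) and stmn2a (33.8-fold, interval 5.73 to 1369, adjusted p = 0.0024). Not called were pdgfrb (-0.21 ± 0.26), pdgfra (0.14 ± 0.30) and col1a1a (-0.62 ± 0.29), at adjusted p = 0.15 to 0.79. 2425 of 12188 genes passed, 1352 higher and 1073 lower, with 1448 without unlesioned 1, 806 without unlesioned 2 and 936 without 24hpl 2 and 97 without cluster 44. Without that cluster fn1a was at 0.28 and tnc at -0.14. Without 1 library calls ended (adjusted p) for col12a1a (unlesioned 1 or 2, 6hpl 1 or 2, 24hpl 1 or 2, 0.063 to 0.21), col12a1b (unlesioned 1 or 2, 6hpl 1, 24hpl 1, 0.0513 to 0.17), fn1b (unlesioned 1 or 2, 24hpl 1, 0.071 to 0.43), ccnb1 (unlesioned 2, 0.082), plk1 (unlesioned 2, 0.087) and stmn2a (unlesioned 2, 0.060). The fold moved over 1.5 times for fn1b (24hpl 2 at 2.58, 24hpl 1 at 0.50), hbae1 (unlesioned 1 at -4.73, unlesioned 2 at -8.24), ccnb1 (unlesioned 1 at 4.77, 24hpl 2 at 3.39, unlesioned 2 at 3.1), hbbe1.1 (unlesioned 1 at -4.53, unlesioned 2 at -7.22, 24hpl 1 at -7.61, 24hpl 2 at -5.8) and hbbe2 (unlesioned 1 at -4.93, unlesioned 2 at -8.02, 24hpl 2 at -6.39). Too few UMIs for a fold (at most 3) were left for hbbe2 (24hpl 1).

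Higher in fibroblast-like cells at 48hpl were the protease gene htra1b (4.69 ± 0.37, adjusted p = 2.3e-05), the tight junction gene cldn11a (4.69 ± 0.64, adjusted p = 0.0039), the clusterin gene clu (4.2 ± 0.45, adjusted p = 6.0e-04) and the interferon-induced gene ifitm1 (4.09 ± 0.65, adjusted p = 0.0071), and lower were pvalb8 (-3.27 ± 0.60, adjusted p = 0.018), the heat shock gene hsph1 (-2.64 ± 0.42, adjusted p = 0.0076) and mbpa (-2.41 ± 0.39, adjusted p = 0.010). Of inflammatory genes, 4 of 19 rose (7 adjusted over the list alone), camera adjusted p = 6.7e-14, adjusted p = 0.11 with an estimated correlation. Examples were lepb (56.9-fold, interval 10.1 to 2259, adjusted p = 0.0042) and cxcl8b.1 (3.08 ± 0.45). Of complement genes, 2 of 7 rose (4 adjusted over the list alone), camera adjusted p = 6.7e-14, adjusted p = 0.13 with an estimated correlation. Examples were si:dkey-8k3.2 (at least 308-fold higher, adjusted p = 2.6e-06), a synonym of c4b, and c7a (2.13 ± 0.24). Of matrix proteases and their inhibitors, 4 of 19 rose (8 adjusted over the list alone), camera adjusted p = 1.0e-12, adjusted p = 0.26 with an estimated correlation. Examples were timp2b (2.41 ± 0.34) and adamts15a (2.67 ± 0.47). Of neuron transcripts, 1 of 11 fell (8 adjusted over the list alone), camera adjusted p = 3.0e-07, adjusted p = 0.46 with an estimated correlation, the called one being snap25a (-2.27 ± 0.42), and sncb did not pass (-2.5 ± 0.72, adjusted p = 0.17). None of the 8 fixed genes was called by edgeR: fn1b (2.28 ± 0.53), fn1a (0.19 ± 0.26), tnc (0.42 ± 0.26), col12a1a (0.65 ± 0.26), col12a1b (0.78 ± 0.27), col1a1a (-0.055 ± 0.29), pdgfrb (-0.41 ± 0.25) and pdgfra (0.38 ± 0.28), at adjusted p = 0.065 to 0.98. At 48hpl 108 of 12188 genes passed, 85 higher and 23 lower, with 48 without unlesioned 1 and 16 without unlesioned 2, and 84 without cluster 44. Lost without 1 library (adjusted p) were calls of cldn11a (unlesioned 2, 0.11), pvalb8 (unlesioned 1 or 2, 48hpl 1, 0.064 to 0.14), hsph1 (unlesioned 2, 0.14), mbpa (unlesioned 2, 48hpl 1, 0.061 to 0.27), lepb (unlesioned 2, 0.13), timp2b (unlesioned 2, 0.10), adamts15a (unlesioned 1 or 2, 0.071 to 0.083) and snap25a (unlesioned 2, 48hpl 2, 0.10 to 0.60). Folds moved over 1.5 times for pvalb8 (48hpl 2 at -4.48, 48hpl 1 at -2.57), hsph1 (unlesioned 2 at -2.02), cxcl8b.1 (unlesioned 2 at 3.95) and snap25a (unlesioned 2 at -1.15). With at most 3 UMIs left no fold is given for ifitm1 (unlesioned 2) and adamts15a (unlesioned 2).

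Fibroblast-like cells were also compared between 24hpl and 6hpl, directly. Higher at 24hpl were the mitotic genes cdk1 (4.03 ± 0.53, adjusted p = 0.0011), spdl1 (3.93 ± 0.78, adjusted p = 0.010), ube2c (3.84 ± 0.52, adjusted p = 0.0015) and ccnb3 (3.81 ± 0.70, adjusted p = 0.0067), and of the fixed genes fn1a (1.9 ± 0.26, adjusted p = 0.0016) and tnc (1.95 ± 0.27, adjusted p = 0.0015). Lower were the globin genes hbbe1.2 (174-fold, interval 31 to 6890, adjusted p = 0.033), hbae3 (-5.49 ± 1.16, adjusted p = 0.015) and hbae1 (-4.9 ± 1.18, adjusted p = 0.027). The rule for named genes was applied to this contrast only after its values were seen. Not called were pdgfrb (-0.78 ± 0.25), pdgfra (-0.076 ± 0.29), col12a1a (0.65 ± 0.26), col12a1b (0.70 ± 0.27), fn1b (-0.031 ± 0.48) and col1a1a (0.39 ± 0.29), at adjusted p = 0.084 to 0.99. 736 of 12188 genes passed, 449 higher and 287 lower, with 178 without 6hpl 1, 175 without 6hpl 2 and 275 without 24hpl 2, and 11 without cluster 44, where none of the named calls held (adjusted p = 0.061 to 0.56). Fitted log2 changes were then 3.31 to 4.3 for the mitotic genes, 0.65 for fn1a, 0.43 for tnc and -5.79 to -4.54 for the globin genes. Calls lost without 1 library (adjusted p) were of spdl1 (6hpl 1 or 2, 24hpl 2, 0.0525 to 0.077), ccnb3 (24hpl 2, 0.056), hbbe1.2 (6hpl 2, 24hpl 1 or 2, 0.083 to 0.20), hbae3 (6hpl 2, 24hpl 2, 0.10 to 0.11) and hbae1 (6hpl 2, 24hpl 1 or 2, 0.082 to 0.17). The fold moved by over 1.5 times for spdl1 (24hpl 2 at 3.3), ube2c (6hpl 2 at 4.92), hbae3 (6hpl 1 at -6.2, 6hpl 2 at -4.13, 24hpl 2 at -4.6) and hbae1 (6hpl 2 at -3.89). At most 3 UMIs, and no fold, were left for spdl1 (6hpl 2), ccnb3 (6hpl 2) and hbae3 (24hpl 1).

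**Figure D2:**
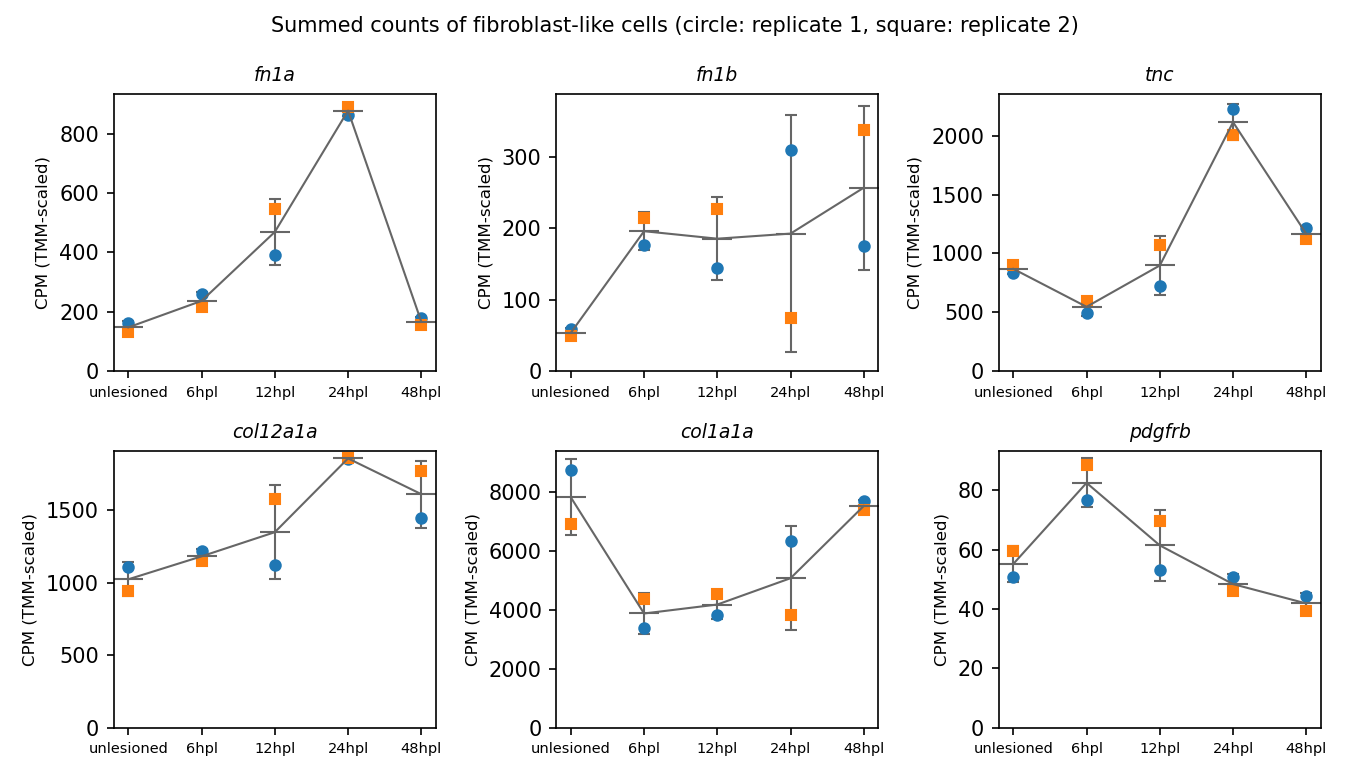
CPM (TMM-scaled counts, vertical axes) of 6 fixed genes in the summed counts of fibroblast-like cells, by group (horizontal axes). Circles and squares are the 2 libraries, line and bars their mean ± SD. fn1a went from 147 CPM in unlesioned larvae to 877 CPM at 24hpl.

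Unlesioned libraries held 3 and 11 macrophage-like cells, under the minimum of 20, so macrophage-like cells were compared between 24hpl and 6hpl. Higher at 24hpl were the transferrin gene tfa (156-fold, interval 43.1 to 1292, adjusted p = 0.011), the chemokine genes ccl38.6 (4.77 ± 0.99, adjusted p = 0.031) and ccl35.1 (4.0 ± 0.64, adjusted p = 0.011) and the retinol carrier gene rbp4 (3.73 ± 0.65, adjusted p = 0.014). Lower were crhbp (at least 44.9-fold lower, adjusted p = 0.011), the collagenase gene mmp13a (-5.86 ± 0.32, adjusted p = 4.8e-06), which went from 485 ± 99.6 to 8.46 ± 1.35 CPM, and the globin gene hbae3 (-5.11 ± 0.84, adjusted p = 0.011). These genes, too, were picked by the rule after the values were seen. In this class 247 of 9251 genes passed, 171 higher and 76 lower, with 81 without 6hpl 1, 107 without 6hpl 2 and 105 without 24hpl 2, and 83 under the coarser clustering. Under that clustering alone the class was tested against unlesioned larvae, with 404 genes at 6hpl, 601 at 12hpl, 421 at 24hpl and 14 at 48hpl called. Leaving out 1 library ended calls (adjusted p) of tfa (6hpl 1 or 2, 0.059 to 0.092), ccl38.6 (6hpl 1 or 2, 24hpl 1, 0.065 to 0.18), ccl35.1 (6hpl 1 or 2, 0.055 to 0.098), rbp4 (6hpl 1 or 2, 0.075 to 0.12) and hbae3 (6hpl 2, 0.15). Fold moves over 1.5 times were of ccl38.6 (24hpl 1 at 3.81), ccl35.1 (24hpl 1 at 4.63, 24hpl 2 at 3.03), rbp4 (24hpl 1 at 4.45, 24hpl 2 at 2.39) and hbae3 (6hpl 2 at -3.61). No fold is given, at most 3 UMIs being left, for hbae3 (24hpl 1).

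In neural progenitor-like cells at 6hpl genes that rose included 4 without a UMI in unlesioned larvae: nppb (at least 188-fold higher, adjusted p = 0.0018), a natriuretic peptide gene, the complement gene c7b (at least 167-fold higher, adjusted p = 1.7e-04), cyp27c1 (at least 132-fold higher, adjusted p = 8.9e-05), a retinoid enzyme gene, and the peptide hormone gene pyya (at least 81.1-fold higher, adjusted p = 0.0016). Genes that fell, with no UMI at 6hpl, included abcc1 (at least 12.3-fold lower, adjusted p = 8.6e-04), fabp7b (at least 11.5-fold lower, adjusted p = 0.0023), a fatty acid binding protein gene, and gas2b (at least 10.7-fold lower, adjusted p = 0.0018). Of genes of progenitor identity, 8 of 20 fell and 1 rose (8 fell and 1 rose, adjusted over the list alone), camera adjusted p = 0.0027, adjusted p = 0.74 with an estimated correlation. Examples were hepacama (-2.91 ± 0.33) and the glial filament gene gfap (-2.62 ± 0.35), which went from 15057 ± 1818 to 2422 ± 1142 CPM. Of ribosome biogenesis genes, 17 of 27 rose (20 adjusted over the list alone), camera adjusted p = 5.1e-10, adjusted p = 0.52 with an estimated correlation. Examples were nop58 (2.22 ± 0.33) and dkc1 (2.51 ± 0.39). Of axon growth and injury response genes, 8 of 20 rose (9 adjusted over the list alone), camera adjusted p = 6.2e-06, adjusted p = 0.29 with an estimated correlation. Examples were the cytokine receptor gene crlf1a (117-fold, interval 39.1 to 576, adjusted p = 1.3e-04) and socs3b (2.52 ± 0.34), genes of cytokine signalling. Superficial epidermis transcripts fell beside them: 3 of 8 fell (4 adjusted over the list alone), camera adjusted p = 0.0052, adjusted p = 0.74 with an estimated correlation. Examples were icn (-3.3 ± 0.71) and cyt1 (-2.98 ± 0.79). In total 1180 of 7616 genes passed, 532 higher and 648 lower, and 546 without unlesioned 1, 599 without unlesioned 2 and 342 without 6hpl 2. The 6hpl libraries held 27 and 71 cells of the class. Without 1 library calls ended (adjusted p) for pyya (6hpl 2, 0.31), fabp7b (6hpl 2, 0.078), gas2b (6hpl 2, 0.069), dkc1 (6hpl 2, 0.089), icn (6hpl 2, 0.13) and cyt1 (unlesioned 2, 6hpl 1 or 2, 0.0547 to 0.18). The fold moved over 1.5 times for gfap (6hpl 2 at -3.26), dkc1 (6hpl 2 at 1.75) and icn (unlesioned 1 at -2.68).

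At 12hpl genes that rose in neural progenitor-like cells included cyp27c1 (at least 126-fold higher, adjusted p = 3.7e-05), nppb (at least 107-fold higher, adjusted p = 0.0019), tnfaip2b (at least 103-fold higher, adjusted p = 1.0e-04) and the cytokine il11a (at least 38.9-fold higher, adjusted p = 5.8e-04). Lower were cyp2ad2 (at least 32-fold lower, adjusted p = 0.0050), fabp7b (105-fold, interval 18.5 to 4193, adjusted p = 3.9e-04) and cyp2ad6 (70.8-fold, interval 12.3 to 2835, adjusted p = 4.4e-04). Of ribosome biogenesis genes, 18 of 27 rose (21 adjusted over the list alone), camera adjusted p = 3.4e-08, adjusted p = 0.52 with an estimated correlation. Examples were dkc1 (2.46 ± 0.37) and nop58 (1.92 ± 0.32). Of unfolded protein response genes, 11 of 21 rose (11 adjusted over the list alone), camera adjusted p = 2.1e-04, adjusted p = 0.42 with an estimated correlation. Examples were dnajb11 (2.84 ± 0.47) and pdia4 (2.06 ± 0.36). Of inflammatory genes, 6 of 14 rose (6 adjusted over the list alone), camera adjusted p = 0.0033, adjusted p = 0.29 with an estimated correlation. Examples were the chemokine ccl19a.1 (3.88 ± 0.51) and il11a. Of superficial epidermis transcripts, 6 of 8 fell (7 adjusted over the list alone), camera adjusted p = 0.0022, adjusted p = 0.74 with an estimated correlation. Examples were krt17 (-4.18 ± 0.92) and icn (-2.67 ± 0.62). At this time 2001 of 7616 genes passed, 953 higher and 1048 lower, and 839 without unlesioned 1, 863 without unlesioned 2 and 472 without 12hpl 1. Lost without 1 library (adjusted p) were calls of cyp2ad2 (unlesioned 1, 12hpl 1, 0.056 to 0.069), krt17 (12hpl 1, 0.11) and icn (unlesioned 1, 12hpl 1, 0.066 to 0.12). Folds moved over 1.5 times for krt17 (unlesioned 2 at -3.51, 12hpl 1 at -3.44) and icn (12hpl 2 at -3.41, unlesioned 1 at -1.99, 12hpl 1 at -2.08). With at most 3 UMIs left no fold is given for krt17 (12hpl 2).

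In neural progenitor-like cells at 24hpl genes that rose included tnfaip2b (at least 168-fold higher, adjusted p = 5.8e-05), nppb (at least 82.2-fold higher, adjusted p = 0.0019), cyp27c1 (at least 92.6-fold higher, adjusted p = 5.8e-05) and il11a (at least 60.6-fold higher, adjusted p = 2.3e-04), and genes that fell included abi3bp (at least 27.8-fold lower, adjusted p = 0.0012), hbae1 (469-fold, interval 129 to 3877, adjusted p = 0.0021) and cyp26a1 (at least 22.3-fold lower, adjusted p = 6.6e-04), a retinoic acid degrading enzyme gene. Of the cell cycle list, 12 of 28 rose (14 adjusted over the list alone), camera adjusted p = 7.9e-06, adjusted p = 0.74 with an estimated correlation. Examples were pcna (2.17 ± 0.31), which went from 121 ± 19.95 to 545 ± 135 CPM, and mcm3 (2.24 ± 0.45). Of unfolded protein response genes, 11 of 21 rose (12 adjusted over the list alone), camera adjusted p = 3.1e-06, adjusted p = 0.29 with an estimated correlation. Examples were pdia4 (2.7 ± 0.36) and manf (2.71 ± 0.38). Erythrocyte transcripts fell in the same cells: 8 of 9 fell (9 adjusted over the list alone), camera adjusted p = 7.3e-04, adjusted p = 0.74 with an estimated correlation. Examples were hbbe1.3 (-8.69 ± 1.56) and hbae1. Here 2170 of 7616 genes passed, 1017 higher and 1153 lower, and 1100 without unlesioned 1, 999 without unlesioned 2 and 1046 without 24hpl 2. The fold moved by over 1.5 times for hbbe1.3 (unlesioned 1 at -5.16, unlesioned 2 at -9.58, 24hpl 2 at -7.33). At most 3 UMIs, and no fold, were left for hbbe1.3 (24hpl 1).

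At 48hpl tnfaip2b (at least 77.9-fold higher, adjusted p = 1.7e-04), cyp27c1 (at least 40.2-fold higher, adjusted p = 1.7e-04), il11a (at least 34-fold higher, adjusted p = 5.7e-04) and the spinal cord patterning gene nkx2.9 (at least 11.4-fold higher, adjusted p = 0.0026) rose in neural progenitor-like cells, and abi3bp (126-fold, interval 41.8 to 624, adjusted p = 4.1e-04), cyp2ad2 (-6.5 ± 1.04, adjusted p = 0.0014) and cnfn (-6.12 ± 0.74, adjusted p = 2.0e-04) fell. Of cell cycle genes, 13 of 28 rose (22 adjusted over the list alone), camera adjusted p = 3.1e-07, adjusted p = 0.71 with an estimated correlation. Examples were pcna (1.76 ± 0.31) and mcm3 (1.88 ± 0.44). Of unfolded protein response genes, 11 of 21 rose (13 adjusted over the list alone), camera adjusted p = 3.7e-07, adjusted p = 0.29 with an estimated correlation. Examples were pdia4 (2.63 ± 0.35) and pdia3 (2.08 ± 0.31). Of axon growth and injury response genes, 9 of 20 rose and 1 fell (12 rose and 1 fell, adjusted over the list alone), camera adjusted p = 9.7e-05, adjusted p = 0.29 with an estimated correlation. Examples were the tubulin gene tubb5 (3.68 ± 0.42) and socs3b (2.8 ± 0.33). Basal epidermis transcripts moved down with these groups: 5 of 7 fell (6 adjusted over the list alone), camera adjusted p = 0.0054, adjusted p = 0.74 with an estimated correlation. Examples were fras1 (-2.45 ± 0.40) and krtt1c19e (-2.57 ± 0.64). 1762 of 7616 genes passed, 768 higher and 994 lower, with 623 without unlesioned 1, 762 without unlesioned 2, 988 without 48hpl 1 and 915 without 48hpl 2. RLE size factors moved the median change of all genes in this class by -0.13 at 12hpl, -0.13 at 24hpl and -0.12 at 48hpl, against TMM. By DESeq2 523 were higher and 875 lower at 12hpl, 573 and 989 at 24hpl and 400 and 808 at 48hpl, while without a gene filter 1292 were higher and 948 lower at 48hpl. Leaving out 1 library ended calls (adjusted p) of cyp2ad2 (unlesioned 1, 0.0528), mcm3 (unlesioned 1, 48hpl 2, 0.062 to 0.10) and krtt1c19e (unlesioned 1, 0.075). Fold moves over 1.5 times were of cyp2ad2 (unlesioned 1 at -5.14), cnfn (unlesioned 1 at -4.82, unlesioned 2 at -6.73), tubb5 (unlesioned 1 at 3.06, unlesioned 2 at 4.88) and krtt1c19e (48hpl 1 at -1.76, 48hpl 2 at -4.47). No fold is given, at most 3 UMIs being left, for cyp2ad2 (48hpl 1 or 2).

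Neuron-like cells at 6hpl had more transcripts of genes known from injured neurons. Of axon growth and injury response genes, 10 of 28 rose (15 adjusted over the list alone), camera adjusted p = 1.3e-13. The transcription factor genes atf3 (3.13 ± 0.32), which went from 268 ± 49.3 to 2361 ± 134 CPM, and stat3 (2.57 ± 0.26) had the smallest p of the list. Of synapse and channel genes, 7 of 34 fell (20 adjusted over the list alone), camera adjusted p = 2.7e-07, adjusted p = 0.18 with an estimated correlation. Examples were the glycine transporter gene slc6a5 (-1.8 ± 0.34) and the receptor subunit gene gabrb2 (-1.35 ± 0.28). Also higher were the leptin gene lepa (5.66 ± 0.47, adjusted p = 7.2e-05), timp2b (4.99 ± 0.64, adjusted p = 9.5e-04), tcap (3.8 ± 0.39, adjusted p = 3.0e-04) and cbx7a (3.49 ± 0.34, adjusted p = 3.0e-04), and lower were the glial genes gfap (-3.5 ± 0.82, adjusted p = 0.031), mbpa (-3.36 ± 0.41, adjusted p = 8.2e-04) and cldnk (-3.21 ± 0.42, adjusted p = 0.0010). Of superficial epidermis transcripts, 2 of 9 fell (4 adjusted over the list alone), camera adjusted p = 0.0090, adjusted p = 0.81 with an estimated correlation. Examples were cyt1l (-2.2 ± 0.40) and cyt1 (-1.73 ± 0.44). In neuron-like cells 573 of 14521 genes passed, 184 higher and 389 lower, and 122 without unlesioned 1, 99 without 6hpl 1 and 221 without 6hpl 2. Without 1 library calls ended (adjusted p) for slc6a5 (unlesioned 1, 6hpl 1 or 2, 0.077 to 0.094), gabrb2 (unlesioned 1 or 2, 6hpl 1 or 2, 0.065 to 0.15), gfap (unlesioned 1, 6hpl 1, 0.15 to 0.19), cyt1l (6hpl 2, 0.074) and cyt1 (unlesioned 1 or 2, 6hpl 1 or 2, 24hpl 1 or 2, 0.057 to 0.21). The fold moved over 1.5 times for timp2b (6hpl 1 at 5.73, 6hpl 2 at 3.78), gfap (6hpl 2 at -5.24, unlesioned 1 at -2.3, 6hpl 1 at -2.67) and mbpa (6hpl 1 at -2.67, 6hpl 2 at -4.52).

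At 12hpl 15 of 28 injury response genes rose and 2 fell in neuron-like cells (17 rose and 2 fell, adjusted over the list alone), camera adjusted p = 3.5e-12. Examples were atf3 (3.4 ± 0.32) and stat3 (2.07 ± 0.26). Of synapse and channel genes, 22 of 34 fell (24 adjusted over the list alone), camera adjusted p = 4.6e-10, adjusted p = 0.12 with an estimated correlation. Examples were the synaptic vesicle gene syt2a (-1.41 ± 0.23) and the glutamate receptor gene gria2a (-1.36 ± 0.23). Of ribosome biogenesis genes, 9 of 28 rose (16 adjusted over the list alone), camera adjusted p = 1.6e-09, adjusted p = 0.40 with an estimated correlation. Examples were nolc1 (1.25 ± 0.25) and gnl3 (1.18 ± 0.24). Also higher were lepa (7.2 ± 0.44, adjusted p = 1.3e-06), gck (72.2-fold, interval 24.5 to 352, adjusted p = 2.9e-05), cremb (5.32 ± 0.38, adjusted p = 5.6e-06) and timp2b (5.11 ± 0.64, adjusted p = 4.5e-04). Lower were pvalb8 (-4.88 ± 0.59, adjusted p = 3.4e-04), the opioid peptide gene pdyn (-4.78 ± 1.15, adjusted p = 0.017) and s100t (-3.3 ± 0.58, adjusted p = 0.0028). In neutrophil-like cells pvalb8 (-4.49) and s100t (-5.55) fell too. Of superficial epidermis transcripts 2 of 9 fell (4 adjusted over the list alone), camera adjusted p = 0.021, adjusted p = 0.81 with an estimated correlation. Examples were cyt1l (-2.18 ± 0.40) and krt17 (-2.11 ± 0.60). Cluster 17 was the largest of the class in unlesioned larvae and at 48hpl, cluster 13 at 6hpl and cluster 39 at 12hpl and 24hpl. At 12hpl 1747 of 14521 genes passed, 598 higher and 1149 lower, with 615 without unlesioned 1, 1073 without unlesioned 2, 507 without 12hpl 1 and 1059 without 12hpl 2, and 358 without cluster 39. Lost without 1 library (adjusted p) were calls of gria2a (12hpl 1, 0.058), pdyn (unlesioned 1, 12hpl 1 or 2, 0.055 to 0.23), cyt1l (12hpl 1, 0.058) and krt17 (unlesioned 1 or 2, 12hpl 1, 24hpl 1 or 2, 0.0542 to 0.25). Folds moved over 1.5 times for pvalb8 (12hpl 1 at -3.96, 12hpl 2 at -5.82), pdyn (unlesioned 2 at -5.65, unlesioned 1 at -2.49), s100t (12hpl 1 at -2.35, 12hpl 2 at -4.35) and krt17 (12hpl 2 at -3.34, 12hpl 1 at -1.23). With at most 3 UMIs left no fold is given for cremb (unlesioned 2).

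At 24hpl the summed neuron-like counts came from 55 and 28 cells, with 148499 UMIs. The growth-associated genes tubb5 (2.26 ± 0.28), which went from 596 ± 201 to 2837 ± 356 CPM, and gap43 (2.41 ± 0.42) were higher, and of the axon growth and injury response list 7 of 28 rose (16 rose and 2 fell, adjusted over the list alone), camera adjusted p = 3.3e-17. Of synapse and channel genes, 10 of 34 fell (17 adjusted over the list alone), camera adjusted p = 3.7e-14, adjusted p = 0.12 with an estimated correlation. Examples were the inhibitory transmitter genes slc32a1 (-3.21 ± 0.40) and slc6a5 (-4.24 ± 0.53). Higher too were gnrh2 (302-fold, interval 45.4 to 12837, adjusted p = 0.0064), il17rel (232-fold, interval 33.1 to 10084, adjusted p = 0.0047), pth1a (124-fold, interval 35.5 to 664, adjusted p = 0.0044) and lepa (6.26 ± 0.64, adjusted p = 6.0e-04), and lower were calb2b (at least 9.18-fold lower, adjusted p = 0.027), cacna2d3 (at least 5.44-fold lower, adjusted p = 0.0044) and cntnap5b (at least 4.82-fold lower, adjusted p = 0.0095). Of erythrocyte transcripts, 5 of 10 fell (6 adjusted over the list alone), camera adjusted p = 7.2e-10, adjusted p = 0.45 with an estimated correlation. Examples were hbbe1.1 (-7.19 ± 1.36) and hbae3 (108-fold, interval 29.8 to 889, adjusted p = 0.027). 308 of 14521 genes passed, 72 higher and 236 lower, and 167 without unlesioned 1, 75 without 24hpl 1 and 20 without 24hpl 2, 120 without cluster 39 and 1 under the stricter cell filter. With RLE size factors 84 were higher and 123 lower, and by DESeq2 182 and 184. With RLE the median change of all genes was 0.20 higher than with TMM. Calls lost without 1 library (adjusted p) were of gap43 (24hpl 2, 0.17), gnrh2 (24hpl 2, 0.13), il17rel (24hpl 1, 0.12), pth1a (24hpl 2, 0.17), calb2b (24hpl 1 or 2, 0.20 to 0.22), cacna2d3 (24hpl 1 or 2, 0.063 to 0.076), cntnap5b (24hpl 1 or 2, 0.11 to 0.12), hbbe1.1 (24hpl 1 or 2, 0.17 to 0.20) and hbae3 (unlesioned 1, 24hpl 1 or 2, 0.098 to 0.27). The fold moved by over 1.5 times for gap43 (24hpl 1 at 3.14, 24hpl 2 at 1.19), slc32a1 (24hpl 1 at -2.56), slc6a5 (24hpl 2 at -3.5) and hbbe1.1 (unlesioned 1 at -4.4, unlesioned 2 at -8.03). At most 3 UMIs, and no fold, were left for slc32a1 (24hpl 2), slc6a5 (24hpl 1) and hbbe1.1 (24hpl 1).

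In neuron-like cells at 48hpl 13 of 28 injury response genes rose (19 adjusted over the list alone), camera adjusted p = 2.1e-16. Examples were the growth-associated gene stmn4 (2.11 ± 0.30) and stat3 (1.73 ± 0.26). Of synapse and channel genes, 4 of 34 fell (7 adjusted over the list alone), camera adjusted p = 0.021, adjusted p = 0.67 with an estimated correlation. Examples were gria2b (-1.22 ± 0.26) and scn1lab (-0.97 ± 0.22). Also higher were lepa (5.15 ± 0.48, adjusted p = 1.8e-04), pimr138 (159-fold, interval 28.2 to 6308, adjusted p = 3.2e-04), the neural stem cell gene msi1 (4.24 ± 0.41, adjusted p = 1.8e-04) and sall1b (4.14 ± 0.34, adjusted p = 7.3e-05), and lower were cnfn (-4.8 ± 0.70, adjusted p = 0.0031), pvalb8 (-4.76 ± 0.59, adjusted p = 0.0010) and the keratin gene krt92 (-4.65 ± 0.79, adjusted p = 0.0062). Superficial epidermis transcripts fell too: 3 of 9 fell (6 adjusted over the list alone), camera adjusted p = 2.6e-05, adjusted p = 0.59 with an estimated correlation. Examples were cyt1l (-2.65 ± 0.42) and icn (-1.93 ± 0.39). At 48hpl 514 of 14521 genes passed, 173 higher and 341 lower, with 180 without unlesioned 1, 322 without unlesioned 2 and 174 without 48hpl 1, and 246 without cluster 39. Leaving out 1 library ended calls (adjusted p) of gria2b (unlesioned 1, 48hpl 1 or 2, 0.085 to 0.19), scn1lab (unlesioned 1 or 2, 12hpl 1 or 2, 24hpl 1 or 2, 48hpl 1 or 2, 0.0504 to 0.26) and icn (48hpl 1, 0.12). Fold moves over 1.5 times were of cnfn (48hpl 1 at -3.19), pvalb8 (48hpl 1 at -3.96), krt92 (unlesioned 2 at -4.04, 48hpl 1 at -3.01) and cyt1l (48hpl 2 at -3.27). No fold is given, at most 3 UMIs being left, for cnfn (48hpl 2) and krt92 (48hpl 2).

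**Figure D3:**
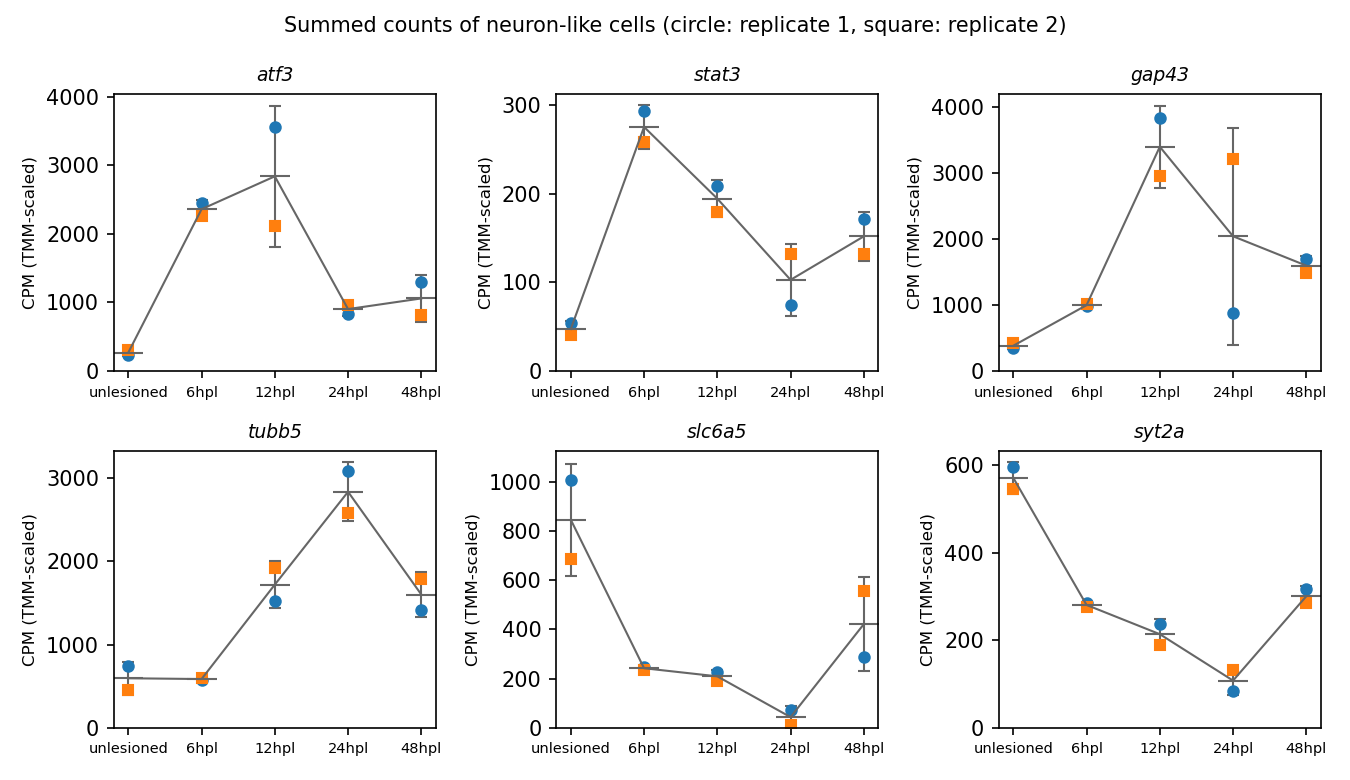
CPM (TMM-scaled counts, vertical axes) of 4 injury response genes (atf3, stat3, gap43, tubb5) and 2 synapse genes (slc6a5, syt2a) in the summed counts of neuron-like cells, by group (horizontal axes). Circles and squares are the 2 libraries, line and bars their mean ± SD. atf3 was at 268 CPM in unlesioned larvae and 2361 CPM at 6hpl.

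In basal epidermis-like cells, the keratinocytes next to the basement membrane, genes that rose at 6hpl included the chemokine cxcl19 (at least 510.4-fold higher, adjusted p = 5.6e-06), the hyaluronan receptor gene cd44a (9.05 ± 0.51, adjusted p = 1.1e-07), the fibronectin gene fn1b (7.66 ± 0.26, adjusted p = 6.2e-09), which went from 7.86 ± 0.273 to 1595 ± 425 CPM, and the desmosome gene pkp1b (7.6 ± 0.27, adjusted p = 6.4e-09). Lower were ucp3 (-5.23 ± 0.39, adjusted p = 7.2e-07), the anchoring fibril collagen gene col7a1 (-3.9 ± 0.20, adjusted p = 6.0e-08) and mgarp (-3.76 ± 0.21, adjusted p = 8.0e-08). Of collagen genes, 13 of 20 fell and 2 rose (14 fell and 2 rose, adjusted over the list alone), camera adjusted p = 4.1e-08, adjusted p = 0.31 with an estimated correlation. Examples were col7a1 and col1a2 (-1.77 ± 0.14). Of inflammatory genes, 17 of 24 rose (19 adjusted over the list alone), camera adjusted p = 6.4e-08, adjusted p = 0.26 with an estimated correlation. Examples were il11a (4.67 ± 0.22) and lepb (5.61 ± 0.45). Unfolded protein response genes were higher: 18 of 22 rose (19 adjusted over the list alone), camera adjusted p = 2.7e-13, adjusted p = 0.081 with an estimated correlation. Examples were manf (2.69 ± 0.17) and hyou1 (2.82 ± 0.18). Superficial epidermis transcripts moved as well: 7 of 10 fell and 1 rose (7 fell and 1 rose, adjusted over the list alone), camera adjusted p = 3.3e-04, adjusted p = 0.26 with an estimated correlation. Examples were icn2 (-2.0 ± 0.24) and krt17 (-2.17 ± 0.26). Of neutrophil transcripts, 4 of 7 rose (4 adjusted over the list alone), camera adjusted p = 0.0018, adjusted p = 0.27 with an estimated correlation. Examples were nccrp1 (3.08 ± 0.26) and srgn (3.09 ± 0.26). 6056 of 15390 genes passed, 3186 higher and 2870 lower. Clusters 31 and 8 held most of the class in unlesioned larvae, and clusters 8, 9 and 32 at 6hpl. Too few UMIs for a fold (at most 3) were left for cd44a (unlesioned 1).

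Basal epidermis-like cells at 12hpl had higher cd44a (9.43 ± 0.51, adjusted p = 9.1e-08), fn1b (7.81 ± 0.26, adjusted p = 5.3e-09) and pkp1b (7.32 ± 0.27, adjusted p = 7.0e-09), and the collagen gene col15a1a (623-fold, interval 213 to 3023, adjusted p = 1.7e-08) rose. The chemokine gene ccl27a (-6.66 ± 0.68, adjusted p = 1.1e-05), ucp3 (-5.47 ± 0.36, adjusted p = 4.1e-07) and col7a1 (-3.92 ± 0.20, adjusted p = 4.7e-08) fell. Of ribosome biogenesis genes, 28 of 28 fell (28 adjusted over the list alone), camera adjusted p = 2.2e-18, adjusted p = 0.26 with an estimated correlation. Examples were ddx21 (-2.6 ± 0.21) and npm1a (-1.61 ± 0.15). Of unfolded protein response genes, 14 of 22 rose and 3 fell (14 rose and 4 fell, adjusted over the list alone), camera adjusted p = 1.2e-11, adjusted p = 0.081 with an estimated correlation. Examples were calr (2.36 ± 0.13) and sdf2l1 (3.15 ± 0.21). Neutrophil transcripts moved up with them: 4 of 7 rose (4 adjusted over the list alone), camera adjusted p = 0.012, adjusted p = 0.33 with an estimated correlation. Examples were nccrp1 (2.77 ± 0.25) and lect2l (5.29 ± 0.51). At 12hpl clusters 9 and 8 held most of the class. There 5682 of 15390 genes passed, 3081 higher and 2601 lower, with 3704 without 12hpl 1. Folds moved over 1.5 times for ccl27a (12hpl 1 at -5.76, 12hpl 2 at -8.13). With at most 3 UMIs left no fold is given for cd44a (unlesioned 1).

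At 24hpl cd44a (8.73 ± 0.51, adjusted p = 1.9e-07), fn1b (8.18 ± 0.26, adjusted p = 1.8e-09), the thrombospondin gene thbs3a (7.24 ± 0.50, adjusted p = 7.6e-07) and the thymosin gene tmsb2 (6.54 ± 0.39, adjusted p = 2.3e-07) rose in basal epidermis-like cells. The globin genes hbae1.3 (-7.73 ± 1.68, adjusted p = 0.0034), hbbe2 (-7.62 ± 1.51, adjusted p = 0.0019) and hbae1 (-7.48 ± 1.91, adjusted p = 0.0089) fell. Of ribosome biogenesis genes, 28 of 28 fell (28 adjusted over the list alone), camera adjusted p = 1.8e-36, adjusted p = 0.21 with an estimated correlation. Examples were npm1a (-2.28 ± 0.15) and wdr43 (-1.67 ± 0.14). Of matrix proteases and their inhibitors, 14 of 21 rose and 2 fell (15 rose and 3 fell, adjusted over the list alone), camera adjusted p = 4.1e-08, adjusted p = 0.21 with an estimated correlation. Among these was adam8a (6.37 ± 0.28). Of complement genes, 4 of 8 rose (4 adjusted over the list alone), camera adjusted p = 1.1e-04, adjusted p = 0.21 with an estimated correlation. Examples were c7a (2.98 ± 0.15) and c6 (4.34 ± 0.45). Transcripts of other cell types fell in the same cells. For erythrocyte genes, 9 of 11 fell (9 adjusted over the list alone), camera adjusted p = 2.1e-04, adjusted p = 0.51 with an estimated correlation. Examples were slc4a1a (-5.69 ± 1.07) and hbbe2. For neuron genes, 9 of 13 fell (10 adjusted over the list alone), camera adjusted p = 1.4e-05, adjusted p = 0.33 with an estimated correlation. Examples were stxbp1a (-4.46 ± 0.47) and elavl4 (-4.04 ± 0.56). Clusters 9 and 8 again held most of the class. In sum 5074 of 15390 genes passed, 2702 higher and 2372 lower, with 2703 without 24hpl 1. Calls lost without 1 library (adjusted p) were of hbae1 (unlesioned 1, 24hpl 1, 0.059 to 0.095). The fold moved by over 1.5 times for thbs3a (unlesioned 1 at 6.09), tmsb2 (24hpl 1 at 5.92), hbae1.3 (unlesioned 1 at -6.75), hbae1 (unlesioned 2 at -8.29, unlesioned 1 at -5.41) and elavl4 (unlesioned 2 at -3.43). At most 3 UMIs, and no fold, were left for cd44a (unlesioned 1), thbs3a (unlesioned 2) and hbae1.3 (24hpl 1).

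At 48hpl basal epidermis-like cells had higher fn1b (6.84 ± 0.25, adjusted p = 1.7e-08), from 7.86 ± 0.273 to 901 ± 197 CPM, twist1a (5.0 ± 0.50, adjusted p = 4.1e-05), a transcription factor gene, and the immune receptor genes gpr84 (4.5 ± 0.37, adjusted p = 1.0e-05) and tnfrsf9a (4.23 ± 0.20, adjusted p = 1.6e-07). Lower were the heat shock gene hsph1 (-2.42 ± 0.23, adjusted p = 3.2e-05), pvalb8 (-2.37 ± 0.28, adjusted p = 1.6e-04) and bhlha9 (-2.19 ± 0.23, adjusted p = 6.2e-05). Of inflammatory genes, 16 of 24 rose (18 adjusted over the list alone), camera adjusted p = 7.8e-28, adjusted p = 0.081 with an estimated correlation. Examples were lepb (6.89 ± 0.42) and il11a (3.53 ± 0.23). Of interferon and antigen presentation genes, 9 of 17 rose (11 adjusted over the list alone), camera adjusted p = 3.5e-11, adjusted p = 0.081 with an estimated correlation. Examples were stat1b (5.89 ± 0.43) and irf9 (1.49 ± 0.17). Of matrix proteases and their inhibitors, 12 of 21 rose (14 rose and 1 fell, adjusted over the list alone), camera adjusted p = 4.9e-12, adjusted p = 0.081 with an estimated correlation. Among these was adam8a (4.57 ± 0.30). Of neuron transcripts, 2 of 13 fell (7 adjusted over the list alone), camera adjusted p = 5.8e-04, adjusted p = 0.43 with an estimated correlation. Examples were stxbp1a (-1.88 ± 0.40) and gng3 (-2.89 ± 0.80). 1386 of 15390 genes passed, 943 higher and 443 lower, with 821 without unlesioned 1, 700 without unlesioned 2, 904 without 48hpl 1 and 664 without 48hpl 2. Leaving out 1 library ended calls (adjusted p) of stxbp1a (unlesioned 2, 48hpl 2, 0.10 to 0.20) and gng3 (unlesioned 2, 6hpl 1 or 2, 12hpl 1 or 2, 48hpl 2, 0.0526 to 0.42). Fold moves over 1.5 times were of twist1a (48hpl 2 at 4.08), gpr84 (unlesioned 1 at 6.17, unlesioned 2 at 3.86), pvalb8 (48hpl 2 at -3.32) and gng3 (unlesioned 2 at -2.18). No fold is given, at most 3 UMIs being left, for stat1b (unlesioned 1) and gng3 (48hpl 1 or 2).

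Gene lists were tested 532 times over the classes and times, and camera called 235 with its preset correlation, of which 177 lie outside 24hpl. With an estimated correlation 4 calls held, those of the axon growth and injury response list in neuron-like cells at the 4 times. The test's sign differed from the list median in 3 called lists and from the list mean in 1. These were the matrix proteases and inhibitors in fibroblast-like cells at 6hpl (median -0.18, mean 0.81, called higher) and in neuron-like cells at 6hpl (median -0.13, mean 0.51, called higher) and 24hpl (median -0.072, mean -0.13, called higher).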

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

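The tests of lower recovery, of loss of neurons around the lesion, of change of expression within each class and of a gained cluster over all list members were chosen only after the result was seen. Values in fibroblast-like cells differed between 24hpl and 6hpl, by edgeR's direct test, for fn1a (log2 difference 1.9, adjusted p = 0.0016), tnc (1.95, adjusted p = 0.0015), vcana (2.27, adjusted p = 0.0020), dkk1a (-2.31, adjusted p = 0.0069), il11 (-1.69, adjusted p = 0.024), mbpa (-6.89, adjusted p = 0.030), hbbe1.2 (-7.06, adjusted p = 0.033) and hbae1 (-4.9, adjusted p = 0.027). The values of mbpa and hbbe1.2 are fitted and no bounds, since 0 and 1 of the 2 libraries at 24hpl held a UMI. Cluster 44 was 25.6% of the class at 6hpl and 36.7% at 24hpl. Without it none of these differences was called, with fn1a (0.65, adjusted p = 0.46), tnc (0.43, adjusted p = 0.56), mbpa (-6.93, adjusted p = 0.22), hbbe1.2 (-5.79, adjusted p = 0.23) and hbae1 (-4.54, adjusted p = 0.19), while il11, dkk1a and vcana did not pass the gene filter. Shares differed between 24hpl and 6hpl for erythrocyte-like (-5.39, adjusted p = 0.0033), fast muscle-like (-4.36, adjusted p = 0.0481) and neuron-like cells (-4.4, adjusted p = 0.0056), and between 48hpl and 24hpl for erythrocyte-like (5.77, adjusted p = 0.0020) and neuron-like cells (3.21, adjusted p = 0.038).

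The share of neuron-like cells was lower at 24hpl. Over all deposited barcodes 14 neuron markers had a median log2 change of -2.83, which argues against the cell filter or naming used here. The authors' cell calling stays open. A candidate is lower recovery of several cell types at 24hpl, where the erythrocyte-like share moved by -5.39 (log2). Loss of neurons around the lesion cannot be told apart from it, because 2 classes outside the spinal cord, picked after their values were seen, fell as well: erythrocyte-like and hair cell-like cells, the latter losing their call without any of 5 libraries. Of 18 classes, 4 were called lower and 2 higher. Of the other 12, 7 were negative (fast muscle-like -3.21, adjusted p = 0.082) and 5 positive (pronephros-like 2.05, adjusted p = 0.11).

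Erythrocyte transcripts were lower at 24hpl in 4 classes, with list medians of -5.82 in fibroblast-like, -7.87 in neural progenitor-like, -4.87 in neuron-like and -6.82 in basal epidermis-like cells, members with at most 3 UMIs (9 of 10 in neuron-like cells) set at their bound. Free RNA from erythrocytes may account for this but was not decided: the log2 ratio of hbae3 to hbbe2 spread over classes within a library with a median SD of 0.519 over 8 libraries, under the bound of 1 set beforehand, but neither 24hpl library had the 20 UMIs of this pair in 3 classes that the test needs. Change of expression within each class stays open too, because the SD of the fitted medians over the classes, 0.441, excludes nothing.

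The axon growth and injury response list was higher in neuron-like cells at the 4 times. Over its 28 tested members the median log2 change at 12hpl was 1.04 without cluster 39 and 1.18 with it, 0.83 to 1.09 without 1 library too, at camera adjusted p = 6.3e-14 (adjusted p = 0.034 with an estimated correlation), which argues against a single gained cluster as the whole cause. The 15 members called higher had a median of 1.24 without it and 1.53 with it, which decides nothing as they were picked by call, and 10 members were called higher without it. After thinning to 71486 UMIs per library their median was 1.59, but thinning keeps the expected fold, so the bound set was wrong and depth stays open. A response of neurons to the lesion, or a change in which neurons were recovered, may also account for the rise, and neither was tested.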

How the results depend on the processing

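Settings added after the data were seen are listed above. Of 289 named gene changes, 289 kept direction and side of the threshold with RLE factors. Calls lost were 10 of 283 by DESeq2, 23 under the stricter cell filter and 12 of 285 with the 2 compared groups alone. Keeping doublets lost 1, a weak check, as only 7.77% to 31.5% of simulated doublets were caught. Without the cluster that rose most, 159 changes in fibroblast-like and neuron-like cells were testable. There 43 lost their call, 10 turned direction, 1 gained a call and 105 did none of these. Genes failing the filter there, such as il11, dkk1a and vcana, were not counted. Of 64 described lists, 4 kept their call with an estimated correlation, 39 by fry and 61 to 63 without 1 library. Class counts held with TMM factors, doublets kept and cells of named classes as the total, and gene counts stayed within 1.5 times by DESeq2, with RLE factors, with doublets kept and without the 24hpl libraries. Whether more genes were higher or lower turned by DESeq2 (basal epidermis 24hpl), at resolution 1 (basal epidermis 6hpl 12hpl 24hpl), with doublets kept (basal epidermis 6hpl 12hpl 24hpl), without a gene filter (basal epidermis 6hpl 12hpl 24hpl, neural progenitor 12hpl 24hpl 48hpl, neuron 12hpl), with the 2 compared groups alone (basal epidermis 24hpl, neuron 12hpl 24hpl), under the stricter cell filter (neural progenitor 6hpl 12hpl, neuron 12hpl 24hpl), without the 24hpl libraries (neuron 12hpl). Where values below changed, the cause was not tested. Some fits had fewer libraries or cells, but without cluster 44 folds of fn1a and tnc at 24hpl fell too. By DESeq2 the values were class counts 2 (6hpl). At resolution 1 the values were gene counts 83 (macrophage 24hpl against 6hpl) and class counts 0 (12hpl, 2 at an unadjusted p under 0.05), 0 (48hpl, 3 at an unadjusted p under 0.05) and reversed log2 changes 0.0025 (pdgfra 24hpl against 6hpl), 0.087 (fn1b 24hpl against 6hpl). With TMM factors on shares the reversed log2 change was -0.34 (share of basal epidermis 12hpl). Called lists were 4 with an estimated correlation and 118 by fry. Without a gene filter the values were gene counts 1678 (fibroblast 6hpl), 422 (fibroblast 48hpl), 1229 (fibroblast 24hpl against 6hpl), 679 (macrophage 24hpl against 6hpl), 1108 (neuron 6hpl), 637 (neuron 24hpl), 1003 (neuron 48hpl), 2108 (basal epidermis 48hpl) and reversed log2 changes 0.061 (col1a1a 48hpl). With the 2 compared groups alone the values were gene counts 1605 (fibroblast 6hpl), 1324 (fibroblast 24hpl), 70 (fibroblast 48hpl), 88 (neuron 24hpl), 222 (neuron 48hpl) and class counts 0 (12hpl, 2 at an unadjusted p under 0.05), 0 (48hpl, 1 at an unadjusted p under 0.05) and reversed log2 changes 0.015 (fn1b 24hpl against 6hpl). Under the stricter cell filter the values were gene counts 63 (fibroblast 48hpl), 1 (neuron 24hpl) and class counts 2 (48hpl) and reversed log2 changes 0.086 (share of fibroblast 6hpl), -0.18 (share of basal epidermis 12hpl), -0.048 (share of basal epidermis 24hpl), -0.054 (tnc 12hpl), -0.12 (fn1a 48hpl). Without the cluster that rose most the values were gene counts 109 (fibroblast 6hpl), 73 (fibroblast 12hpl), 97 (fibroblast 24hpl), 11 (fibroblast 24hpl against 6hpl), 358 (neuron 12hpl), 120 (neuron 24hpl), 246 (neuron 48hpl) and reversed log2 changes -0.37 (fn1a 6hpl), -0.066 (col12a1b 6hpl), -0.17 (col12a1a 6hpl), 0.11 (pdgfra 12hpl), -0.13 (fn1a 12hpl), -0.32 (tnc 12hpl), -0.15 (pdgfrb 12hpl), -0.14 (tnc 24hpl), 0.58 (pdgfra 24hpl against 6hpl), 0.77 (fn1b 24hpl against 6hpl). Without the largest class the share of basal epidermis 12hpl reversed (-0.0060). Replicate numbers recur in the groups without a stated pairing, and deviations of same-numbered libraries correlated at -0.253 to 0.238. With the replicate number as a block, the values that changed were -0.059 (share of neuron 6hpl), 0 (12hpl, 2 at an unadjusted p under 0.05), 0 (48hpl, 3 at an unadjusted p under 0.05), 3 named genes lost their call, and gene and list counts stayed within 1.5 times. Without 1 library, where the lone library of a group is assumed to vary like the other groups, the ranges were for gene counts 225 to 1451 (fibroblast 6hpl), 623 to 2846 (fibroblast 12hpl), 806 to 2516 (fibroblast 24hpl), 16 to 159 (fibroblast 48hpl), 175 to 832 (fibroblast 24hpl against 6hpl), 81 to 312 (macrophage 24hpl against 6hpl), 342 to 1141 (neural progenitor 6hpl), 472 to 2218 (neural progenitor 12hpl), 999 to 2422 (neural progenitor 24hpl), 623 to 2034 (neural progenitor 48hpl), 99 to 616 (neuron 6hpl), 507 to 1893 (neuron 12hpl), 20 to 374 (neuron 24hpl), 174 to 517 (neuron 48hpl), 3704 to 5767 (basal epidermis 12hpl), 2703 to 5222 (basal epidermis 24hpl), 664 to 1401 (basal epidermis 48hpl), and for class counts 0 to 1 (12hpl), 2 to 8 (24hpl), 0 to 1 (48hpl), and for log2 changes -1.18 to 0.93 (share of fibroblast 6hpl), -0.37 to 1.04 (share of neuron 6hpl), -0.072 to 2.04 (share of fibroblast 12hpl), -0.67 to 0.75 (share of neuron 12hpl), -0.23 to 0.44 (share of basal epidermis 12hpl), -1.52 to 0.58 (share of fibroblast 24hpl), -2.5e-04 to 0.60 (share of basal epidermis 24hpl), -0.21 to 1.9 (share of fibroblast 48hpl), -0.70 to 0.11 (pdgfra 12hpl), -0.17 to 0.32 (tnc 12hpl), -0.16 to 0.16 (col1a1a 48hpl), -0.22 to 9.6e-04 (pdgfra 24hpl against 6hpl), -0.077 to 0.70 (col1a1a 24hpl against 6hpl), -1.45 to 0.65 (fn1b 24hpl against 6hpl). Few cells limit the precision for neuron-like cells at 24hpl.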

Other observations

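This class, EGFP and mmp9 were chosen after their values were seen. In neutrophil-like cells at 6hpl edgeR called higher the gelatinase gene mmp9 (4.71 ± 0.59, adjusted p = 0.0011), as log2 change ± standard error with n = 2. Without 1 library its fold moved over 1.5 times (unlesioned 1 at 6.1, unlesioned 2 at 4.09, 6hpl 1 at 4.12). Called in the class were 1689 genes at 6hpl, fewer without 1 library of these groups. EGFP in fibroblast-like cells was at 51.2 and 22.9 CPM (without TMM scaling) unlesioned, 937 and 411 at 6hpl, 879 and 474 at 12hpl, 75.1 and 92.9 at 24hpl and 56.3 and 57.4 at 48hpl. By edgeR it was higher at 6hpl (4.24 ± 0.53, adjusted p = 4.6e-04) and 12hpl (4.32 ± 0.53, adjusted p = 2.7e-04). Without 1 library the log2 change was 3.56 to 5.07. Both calls ended without cluster 44 (3.16 ± 0.78, adjusted p = 0.081 and 2.48 ± 0.77, adjusted p = 0.16). In basal epidermis-like cells, which should lack it, EGFP was at 0.87 and 1.19 CPM unlesioned, 2.19 and 4.25 at 6hpl and 3.8 and 6.16 at 12hpl, and in unnamed clusters at 6.67 and 7.84, 27.8 and 39.7 and 72.8 and 41. Both libraries lay above both unlesioned ones in 11 of 18 other named classes at 6hpl and 16 at 12hpl. The classes share libraries and any free RNA in them, so they are not separate draws. Several held few EGFP UMIs, such as macrophage-like cells (0 unlesioned and 6 at 6hpl). EdgeR called EGFP higher in 2 of 10 classes tested at 6hpl and 3 of 10 at 12hpl. Without 1 library these numbers moved both ways.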
